A study of Homo sapiens with 7 samples.

How the data were processed

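RNA of 4 control and 3 MZB1 knockout samples of the Hs294T melanoma line was measured, per the labels, with a NanoString nCounter immune panel of 785 genes, of which 12 are reference genes. Both deposited tables were used. The first holds raw counts per probe, deposited without normalization, for 773 endogenous genes, 12 reference genes, 6 positive control probes and 8 negative control probes, per the file headers. The lowest raw count was 1 in every sample, and whether the authors subtracted a background is not given in the sources used here. The second table holds log2 values made by the authors. Set against the raw counts, each value equalled log2 of the count plus 1 constant per sample, and the constant matched the geometric mean of the 10 reference genes with a mean count of at least 50, with values below 0 set to 0. Image processing and software of the authors are not given in the sources used here, and no genome build is named, so no coordinates are printed. Samples were grouped and numbered by their titles, and columns were matched to titles by name. Of 785 gene names, 779 were matched to a gene table of the GRCh38.p14 assembly, 753 had the same symbol, 26 were names of probes that cover several genes, and names are given as in the files.

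Library sizes were set from the geometric mean of the same 10 reference genes, and a normalized count is the raw count over this factor. A gene was tested if its raw count was at least 20 in at least 3 of the 7 samples, which left 437 endogenous genes. Of the 336 not tested, 249 had a mean at or under the negative control threshold in both groups. The test was edgeR 4.0.16 quasi-likelihood with robust estimation (R 4.3.3), with Benjamini-Hochberg adjustment over the endogenous genes tested and a threshold of 0.05. The SE of a log2 fold change is its size over the square root of the F statistic. A group was taken to be at background for a gene when its mean was at or under its mean normalized threshold, the mean plus 2 SD of the negative control probes (9.43 in controls, 5.93 in knockout samples). A fold is then given as a bound, with each value of that group under its sample's threshold raised to that threshold before averaging.

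Gene lists were fixed before the data were examined, 36 in all, and the 21 with at least 5 tested genes were tested with camera (limma 3.58.1, preset correlation 0.01) against all other tested genes, with an estimated correlation and fry as alternatives. Named genes were chosen by a rule fixed at the same time. It takes the 12 largest log2 fold changes in each direction among changed genes with a mean of at least 50 in the higher group and no overlap between groups. For each list described it takes up to 4 changed genes with the smallest adjusted p and those against the direction of the list, and it takes the reference gene with the largest change. The rule also named MZB1 itself, which was not analysed here, and some genes the rule takes are not reported here.

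The alternatives were edgeR's TMM and RLE, total counts, positive control probes with reference genes, DESeq2 1.42.0, limma on the authors' log2 values with and without a pseudocount of 20, filters of 0 and 50 counts and of the negative controls, counts below 20 set to 20, no robust estimation, the replicate number as a block, an adjusted p of 0.01, and each sample left out in turn. Scaling on a smaller set of the reference genes and thinning of every library to the shallowest were added after seeing the data. Replicates of a group differed by more than counting noise in each pair (chi-square per degree of freedom 2.55 to 12.6), so none was counted as a duplicate.

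On simulated counts with the means, spread and library sizes of the 437 genes, edgeR recovered 48% of 50 genes changed 1.25-fold, 68% at 1.5-fold, 92% at 2-fold and 98% at 4-fold, and called 1.3% of 237 unchanged genes. Total counts were 217397 to 413477 per sample, and the amount of RNA per sample is not given in the sources used here. Each explanation weighed in the closing observations was given limits that would count for or against it, and those for the control samples and the interferon genes were set after the patterns were seen. For the depth of the control libraries, a second test, thinning, was added after the positions of the control samples were known, and the test first written down was kept beside it.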

Results

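RNA of Hs294T cells, an established human melanoma cell line, was measured in 4 control samples and 3 samples in which MZB1 had been knocked out with CRISPR/Cas9, a nuclease that cuts the genome at a site set by a guide RNA. MZB1 encodes a protein of the endoplasmic reticulum known mainly from B cells and plasma cells. Transcripts were counted directly with barcoded probes on the NanoString nCounter platform, using a panel of 773 endogenous genes of immune and cancer biology and 12 reference genes. Total counts over endogenous and reference genes were 383241, 217397, 270710 and 359499 in control replicates 1 to 4, and 369636, 328813 and 413477 in knockout replicates 1 to 3. Between 455 and 548 genes per sample lay above the mean plus 2 SD of the negative control probes. Levels below are normalized counts, given as mean ± SD (n = 4 control, n = 3 knockout), and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named.

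No probe analysed here was named for MZB1, so the targeted transcript was not analysed here and the group labels rest on the sample titles alone. The labels do not say whether the samples of a group came from separate cultures or edited clones, so the p-values measure only the spread between these samples, which may be technical.

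The comparison asked which immune-related and cancer-related transcripts differ between melanoma cells with and without MZB1. The knockout samples differed from the controls in 298 of the 437 genes tested, of which 138 were higher and 160 lower. SLC2A12, a sugar transporter, rose from 49.9 ± 16.4 to 1242 ± 200.1, and PPARG, a nuclear receptor of lipid metabolism, rose from 145 ± 52.7 to 1056 ± 101. The chemokine CCL2 fell from 9377 ± 660 to 536 ± 121, and NFATC2, a calcium-regulated transcription factor, fell from 2119 ± 142 to 43.1 ± 14.3. The MHC class II genes fell together, and the interferon-stimulated genes moved in both directions.

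Of the changed genes, 143 differed at least 2-fold, 69 upward and 74 downward, and 77 differed at least 4-fold. Every knockout sample lay on the same side of every control sample for 287 of the 298 changed genes, and for 299 of all 437 tested genes, where chance alone gives 5.714%. Correlations of log2 normalized counts across genes, which are not independent replicates, were 0.978 to 0.993 within groups and 0.759 to 0.817 between groups. The first principal component held 91.43% of the variance and separated all control from all knockout samples (two-sided exact permutation p = 0.05714, the smallest that 4 against 3 samples allow). On the deposited normalized values, the log2 fold changes correlated with those from the counts at r = 0.9991 across the 437 genes, and 99.54% had the same sign. Those values are log2 of the same counts under the same reference gene scaling. This agreement therefore holds by construction and is no separate evidence.

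Among the largest rises was that of CCNA1, a cyclin, from 16.5 ± 6.24 to 575 ± 94.9. IDO1, which degrades tryptophan, rose from 63.6 ± 42.0 to 858 ± 102 (log2 fold change 3.82 ± 0.49 SE, adjusted p = 0.00075). EFNA1, an ephrin ligand, rose from 20.9 ± 11.5 to 265 ± 15.1, VAV3, a guanine nucleotide exchange factor, from 43.2 ± 21.8 to 358 ± 70.0, and FPR1, a formyl peptide receptor, from 10.4 ± 3.31 to 129 ± 38.3. Some genes were at the background of the assay in the controls, and their rise is given as a lower bound, the knockout mean over the control mean after each control value under its sample's negative control threshold was raised to that threshold. The bounds were at least 16.2-fold for FABP4, a fatty acid binding protein (adjusted p = 7.9e-06), at least 13.1-fold for CYP26A1, which breaks down retinoic acid, and at least 8.48-fold for CSF1R, the receptor of CSF1.

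Among the largest falls, NFATC2 had a log2 fold change of -5.63 ± 0.18 SE (adjusted p = 1.4e-08) and CCL2 of -4.13 ± 0.16 SE (adjusted p = 8.2e-08). FYN, a Src-family kinase, fell from 570 ± 32.7 to 37.4 ± 3.86, NR4A1, an orphan nuclear receptor, from 242 ± 19.98 to 8.76 ± 2.42, and LPAR1, a lysophosphatidic acid receptor, from 179 ± 26.2 to 8.10 ± 2.46. RXRG, a retinoid X receptor, fell from 429 ± 60.6 to background, at least 69.0-fold with the same kind of bound (adjusted p = 2.1e-09). Falls to background were also at least 13.9-fold for ALDH1A1, a retinaldehyde dehydrogenase, and for RGS16, a regulator of G-protein signalling. They were at least 13.1-fold for FCGR2B, an Fc receptor, and for AQP1, a water channel, at least 13.0-fold for IL16 and at least 12.7-fold for IL10, both cytokines.

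**Figure D1:**
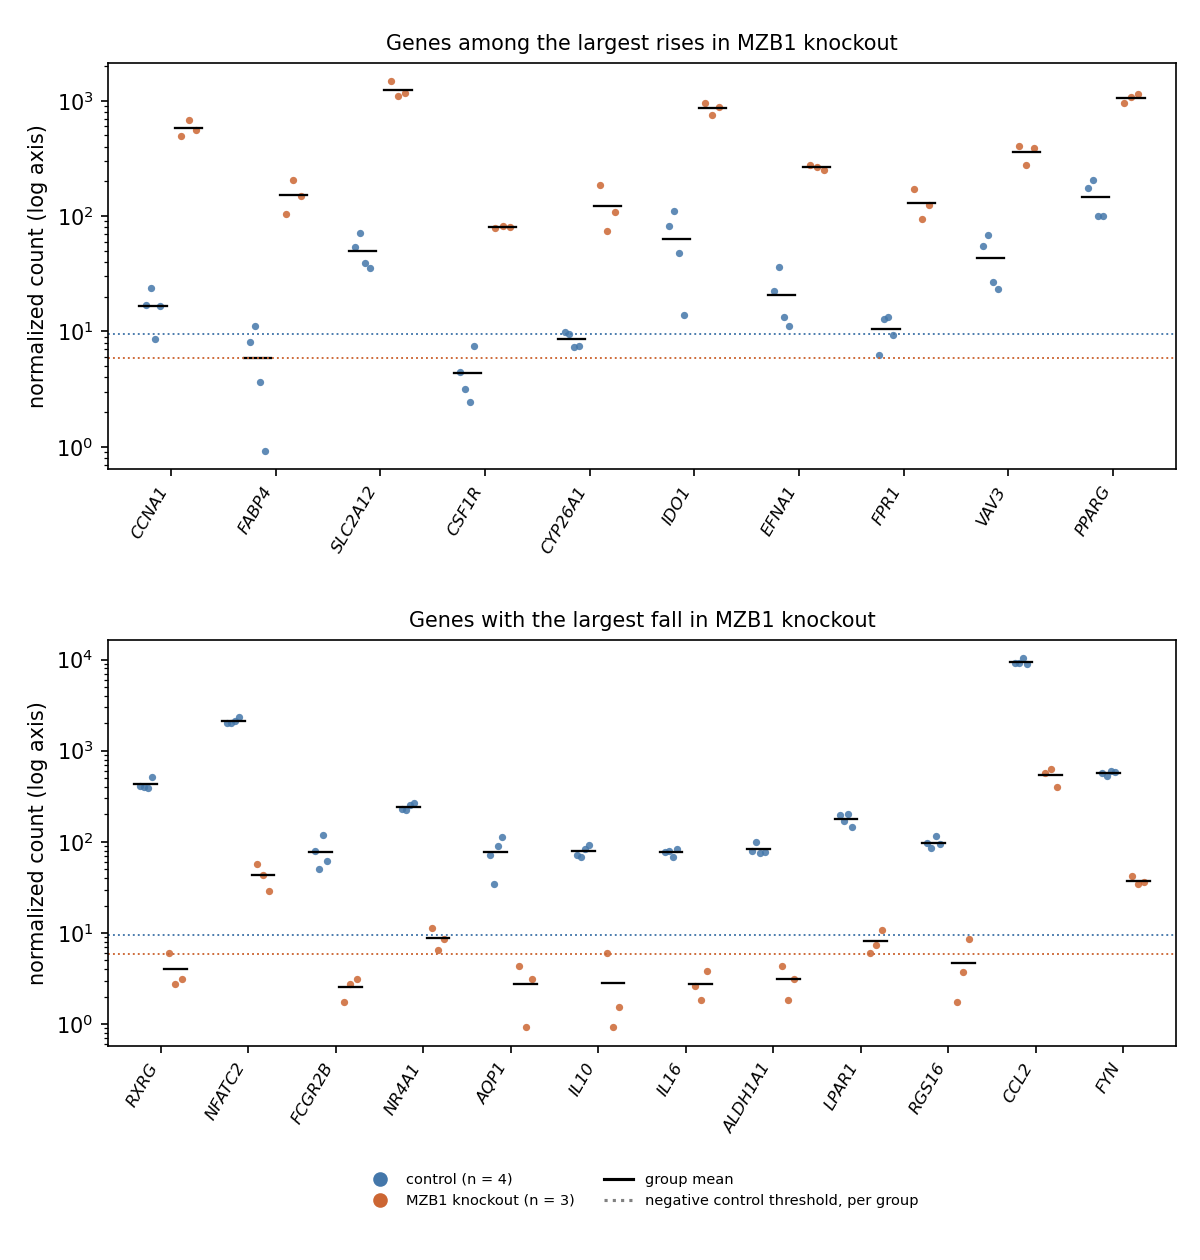
Normalized counts (log axis) of 10 genes among those with the largest rise (top) and the 12 with the largest fall (bottom) in the knockout, 1 point per sample (4 control, 3 knockout), with black bars at the group means and dotted lines at each group's mean negative control threshold. The groups do not overlap for any of these genes, and RXRG lies at a mean of 429 in the controls and has a mean below the threshold in the knockout.

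MHC class II genes, which present antigen to CD4 T cells, fell in the knockout. All 6 tested members were lower, and all 6 were also lower when adjusted over the list alone. HLA-DRA fell from 1673 ± 78.5 to 142 ± 26.4, HLA-DRB1/3 from 781 ± 27.1 to 128.5 ± 18.3, HLA-DPA1 from 636 ± 25.7 to 138 ± 15.2 and HLA-DPB1 from 1175 ± 22.3 to 487 ± 28.5. CIITA, the transactivator of these genes, was below the filter for testing, at 18.3 ± 2.73 in controls and 5.10 ± 0.66, at background, in the knockout; it was named after its values were seen. This was the only list of the 21 tested that passed camera with a preset correlation (adjusted p = 6.9e-06). It did not pass with an estimated correlation (adjusted p = 0.0663), and no list did. Fry, which asks whether the members of a list move on balance 1 way without comparing them with other genes, passed 16 of the 21 lists. No list described below passed camera, and their counts of changed genes are to be read beside the 68.19% changed among all tested genes. Adjustment over a list alone reuses the same p-values and adds little support.

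Among the 5 tested MHC class I genes, 3 rose, 1 fell and 1 did not pass, with the same counts when adjusted over the list alone. The immunoproteasome subunits PSMB9 and PSMB10 rose from 120 ± 19.0 to 257 ± 31.5 and from 44.1 ± 4.67 to 98.9 ± 5.77, and the proteasome activator PSME2 from 521 ± 22.8 to 684 ± 50.4. HLA-E, a non-classical class I molecule, fell from 579 ± 19.8 to 365 ± 8.31.

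Interferon-stimulated genes of the type I list went both ways, with 3 of 10 tested members higher, 4 lower and 3 not passing, and the same counts when adjusted over the list alone. MX1 and MX2, antiviral GTPases, fell from 165 ± 50.5 to 25.6 ± 8.96 and from 162 ± 31.1 to 11.9 ± 0.70. BST2, which tethers budding virus, rose from 277 ± 153 to 954 ± 134, and RSAD2, an antiviral enzyme, rose at least 5.65-fold from background. In the interferon-gamma list, 6 of 11 tested members rose and 1 fell, and the same counts held when adjusted over the list alone. CD274, which encodes PD-L1, rose from 16.3 ± 6.70 to 57.3 ± 5.52, GBP2, a guanylate-binding protein, from 93.1 ± 39.8 to 353 ± 35.5, and FAS, a death receptor, from 237 ± 14.8 to 371 ± 29.8. JAK1 fell from 191 ± 13.9 to 150 ± 6.99 (adjusted p = 0.013), a call lost with total count scaling and with DESeq2's own size factors.

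**Figure D2:**
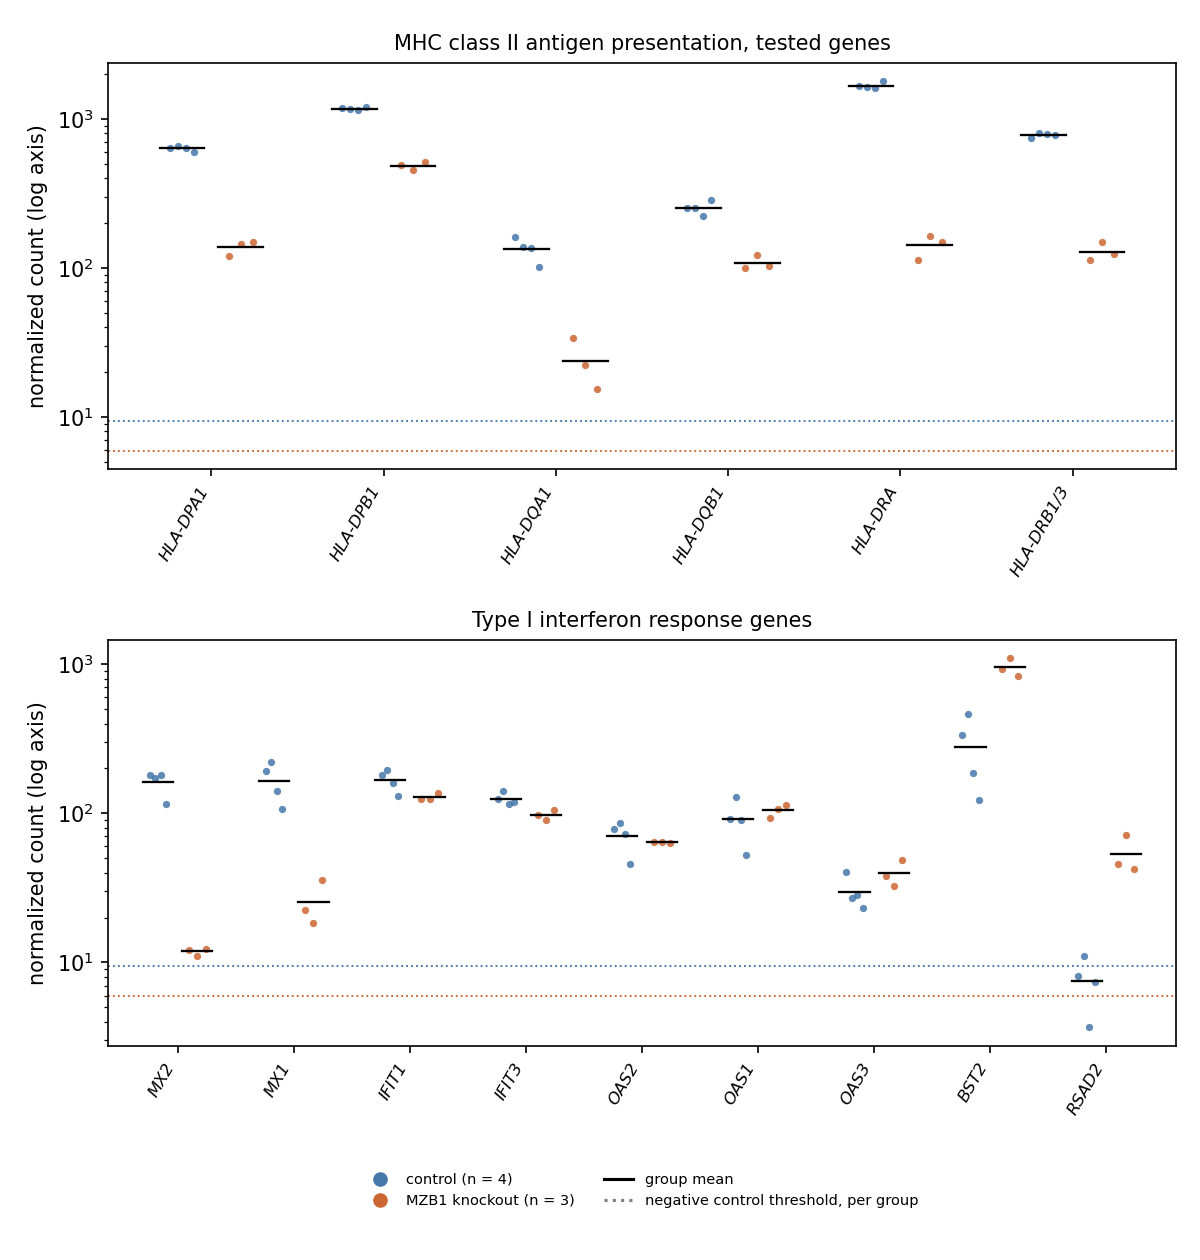
Normalized counts (log axis) of the 6 tested genes of the MHC class II list (top) and 9 of the 10 tested type I interferon response genes (bottom), 1 point per sample (4 control, 3 knockout), with black bars at the group means and dotted lines at each group's mean negative control threshold. All 6 genes of the MHC class II list are lower in every knockout sample, while MX1 and MX2 fall and BST2 and RSAD2 rise.

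Of 18 tested genes of the NF-kB and inflammatory list, 10 fell and 2 rose, also when adjusted over the list alone. The list did not pass camera (adjusted p = 0.62), and 68.19% of all tested genes changed. PTGS2, the inducible cyclooxygenase, fell from 55.9 ± 7.35 to 7.61 ± 2.01, and TNFAIP3, an inhibitor of NF-kB, from 90.7 ± 6.95 to 43.6 ± 3.97. The genes that rose were IL6, from 599 ± 220.1 to 1562 ± 221, and CCL5, from 25.3 ± 3.27 to 122 ± 21.2. Among 5 tested chemokine genes, 3 fell and 1 rose, with the same counts adjusted over the list alone. Beside CCL2, CXCL8 fell from 7096 ± 1671 to 1353 ± 934 and the probe for CXCL1/2/3 from 104 ± 21.6 to 30.3 ± 16.1. The knockout values of CXCL8 were 2430, 853 and 775, and without knockout replicate 1 the CXCL8 log2 fold change went from -2.39 to -3.12.

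Interleukins and their receptors rose in 10 and fell in 5 of 19 tested genes, or 10 and 6 when adjusted over the list alone. IL7R rose from 394 ± 63.8 to 1772 ± 240 and CSF1 from 148 ± 25.5 to 655 ± 125.4. IL1A fell from 129 ± 31.9 to 45.2 ± 11.7, IL1R1 from 30.997 ± 7.91 to 12.8 ± 4.37, and IL24 at least 4.33-fold to background. Among 15 tested checkpoint and co-stimulation genes, 6 rose and 6 fell, also when adjusted over the list alone. CEACAM1, an adhesion receptor, fell from 439.9 ± 82.1 to 91.0 ± 7.63, NT5E and ENTPD1, which make adenosine from extracellular nucleotides, from 273 ± 19.6 to 66.7 ± 16.9 and from 51.1 ± 6.46 to 14.3 ± 3.06, and CD96 from 160 ± 20.1 to 58.0 ± 3.11. Beside IDO1 and CD274, ICOSLG rose from 14.2 ± 5.26 to 48.6 ± 10.5 and TNFSF9 from 529 ± 124 to 998 ± 114. CD276 rose from 1479 ± 59.4 to 1644 ± 64.7 (adjusted p = 0.038), a call lost in 10 of 23 alternatives, among them TMM scaling, no filter, and leaving out control replicate 1, 3 or 4 or knockout replicate 1 or 2, while its log2 fold change stayed between 0.12 and 0.26. VSIR rose at least 2.27-fold from background, a direction that reversed to a log2 fold change of -0.0066 when counts below 20 were set to 20. In the TNF superfamily, 4 of 7 tested genes rose and 2 fell, also over the list alone, with TNFRSF1A from 802 ± 73.0 to 1566 ± 127, CD40 from 65.8 ± 10.1 to 19.1 ± 6.04 and TNFSF4 from 54.7 ± 15.6 to 15.4 ± 2.11.

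WNT signalling genes fell in 4 of 7 tested members and rose in none, also over the list alone, but the list did not pass camera (adjusted p = 0.62). One of the 4, TCF7 (adjusted p = 0.038), lost its call in 8 of 22 alternatives, among them total count scaling, DESeq2's own size factors and 5 runs with 1 sample left out. SFRP1, a secreted WNT antagonist, fell from 3924 ± 72.3 to 899 ± 162, FZD7, a WNT receptor, from 285 ± 12.4 to 94.1 ± 19.9, and LEF1, a WNT-dependent transcription factor, from 202 ± 10.98 to 87.8 ± 22.7. Adhesion and migration genes fell in 8 and rose in 3 of 13 tested members, also over the list alone, without passing camera (adjusted p = 0.68). The integrins ITGB8, ITGA6 and ITGB3 fell, from 5840 ± 454 to 891 ± 188, from 1489 ± 117 to 534 ± 46.1 and from 2971 ± 294 to 1301 ± 194. ITGAV rose from 356 ± 15.8 to 589 ± 40.9, CDC42 from 2562 ± 90.7 to 3346 ± 136, and PECAM1 at least 3.23-fold from background. The PECAM1 call was lost when counts below 20 were set to 20. All 8 tested TGF-beta and mesenchymal genes changed, 5 upward and 3 downward, also over the list alone. TGFB1 rose from 375 ± 53.4 to 936 ± 111 and BMP2 from 235 ± 34.9 to 413 ± 53.1, whereas SMAD4 fell from 713 ± 48.9 to 489 ± 13.8, MMP14 from 3427 ± 309 to 2357 ± 137 and SMAD2 from 1836 ± 76.9 to 1562 ± 42.4.

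DNA damage and p53 response genes fell in 5 of 7 tested members and rose in 1, also over the list alone, without passing camera (adjusted p = 0.62). The damage kinase ATM fell from 1243 ± 77.0 to 622 ± 44.7 and BAX, which promotes apoptosis, from 1566 ± 42.5 to 816 ± 28.5, while the checkpoint kinase CHEK1 rose from 463 ± 21.7 to 624 ± 78.0. Of 9 tested cell cycle genes, 2 fell, E2F1 from 321 ± 31.03 to 206 ± 18.1 and CDKN2C from 996 ± 144 to 531 ± 116, and 7 did not pass. In PI3K-AKT-mTOR signalling 2 of 19 tested genes rose and 5 fell, with PIK3R1, a regulatory subunit, from 346 ± 13.6 to 96.4 ± 8.01. JAK-STAT genes rose in 4 and fell in 6 of 13 tested members, with SOCS2, a feedback inhibitor, from 220.2 ± 38.4 to 45.9 ± 6.18 and IL6ST, a cytokine receptor subunit, from 2856 ± 278 to 5537 ± 377. Apoptosis genes rose in 5 and fell in 2 of 14 tested members, or 4 and 2 over the list alone, and MAPK genes rose in 7 and fell in 5 of 19, or 7 and 4 over the list alone. One of these 5, DUSP1 (adjusted p = 0.0495), lost its call in 11 of 23 alternatives. Metabolic genes of lipids, amino acids and nucleotides rose in 4 and fell in 2 of 9, with SLC7A5, an amino acid transporter, from 2824 ± 442 to 797 ± 172. The dedifferentiated melanoma list had 2 genes higher and 2 lower of 5, and epigenetic regulators 1 higher and 2 lower of 7. The median, mean and test differed in sign for the type I interferon, checkpoint and TNF superfamily lists.

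**Figure D3:**
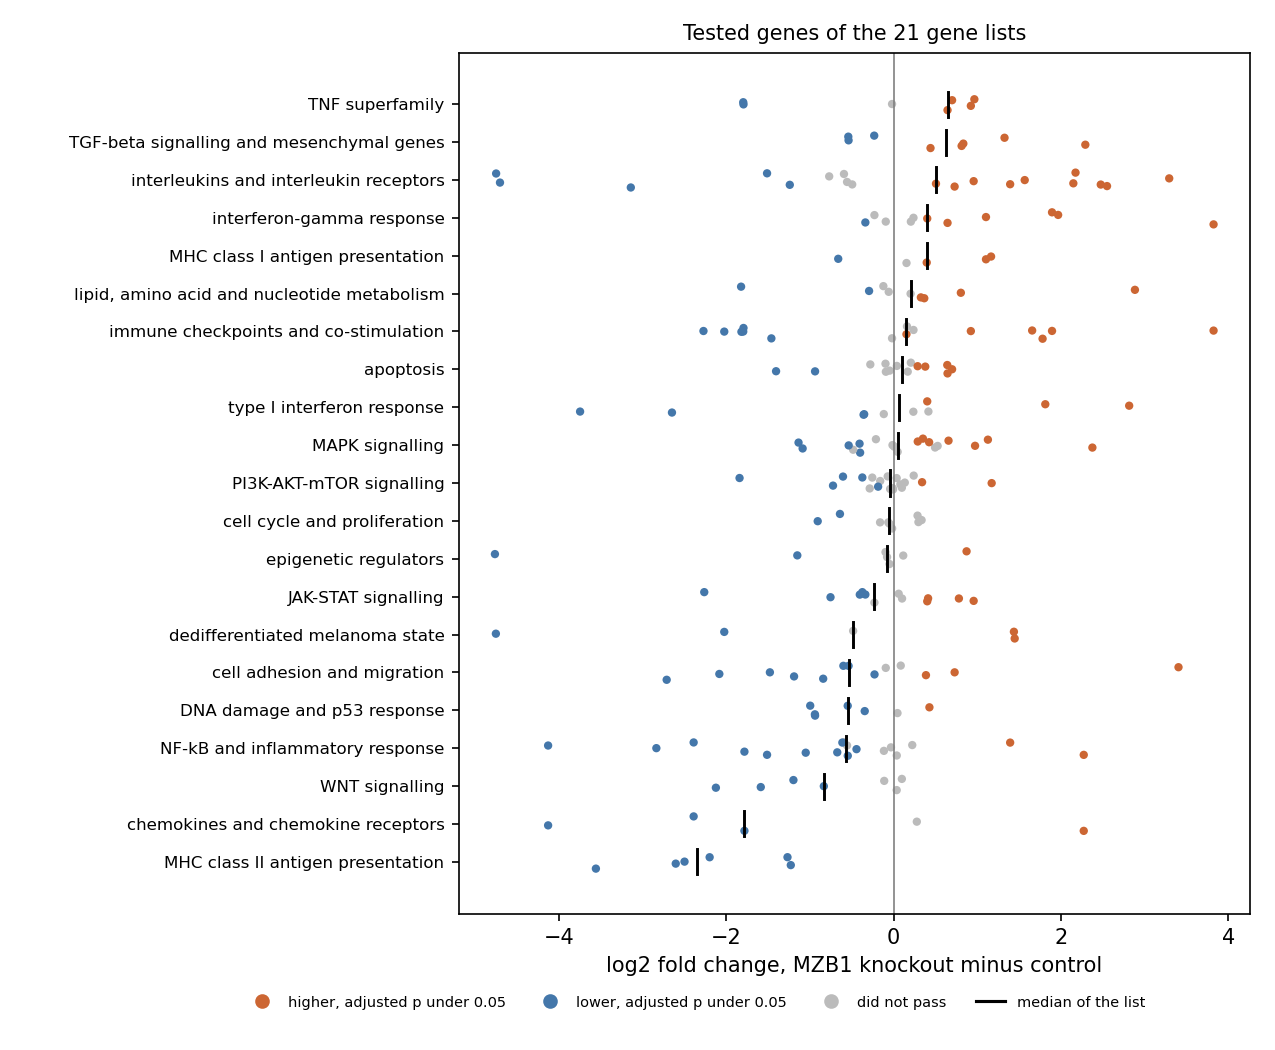
Log2 fold changes (knockout minus control) of all tested genes in the 21 gene lists tested, 1 point per gene, coloured by direction where the adjusted p was under 0.05 and grey otherwise, with black bars at list medians. All 6 MHC class II genes lie below 0, while most other lists hold genes on both sides.

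Markers of other cell types were mostly too low to test, with 3 of 32 T cell genes on the panel, 3 of 19 B and plasma cell genes, 2 of 19 NK cell genes and 4 of 25 myeloid genes above the filter. The leukocyte marker PTPRC was at background in both groups, at 3.20 ± 1.72 and 2.90 ± 1.18. The probe for TRBC1/2, T cell receptor constant regions, rose from 127 ± 38.3 to 672 ± 38.5, and PRDM1, a plasma cell transcription factor, from 52.8 ± 10.3 to 252 ± 55.7. The B cell gene CD22 fell from 137 ± 22.5 to 96.8 ± 2.24 (adjusted p = 0.014), a call lost without control replicate 1, and the NK cell gene KLRG1 from 37.9 ± 6.85 to 18.9 ± 6.36. By list, 1 T cell gene rose and none fell, 2 B and plasma cell genes rose and 1 fell, no NK cell gene rose and 1 fell, and 3 myeloid genes rose and 1 fell. These counts include 2 rises that did not hold throughout: CD68 (adjusted p = 0.030) lost its call in 7 of 23 alternatives and BLK in 2 of 22. The 3 tested fibroblast and endothelial markers rose, among them PDGFRB from 43.4 ± 11.1 to 115 ± 14.9 and DCN at least 5.15-fold from background.

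The scaling factors from 10 reference genes had a coefficient of variation of 21.86% over the 7 samples. The reference gene PGK1, a glycolytic enzyme, itself differed between the groups, from 7190 ± 477 to 4382 ± 282 (log2 fold change -0.71 ± 0.07 SE, adjusted p = 1.0e-05 over the 12 reference genes). OAZ1 rose by 0.29 on the same scale.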

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

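Each control level of a gene named by the rule, and each measure of the control libraries, was checked for 1 sample far from the other 3, and the knockout group of 3 was not checked. Of 139 measures, 8 had such a sample, where chance gives about 6.95. Control replicate 4 stood apart for CCL5 (20.4 against 26.9 to 27.0 in the others), MMP14 (2968 against 3520 to 3632), MX2 (116 against 173 to 180.0) and RXRG (519 against 390.2 to 408). Control replicate 2 stood apart for CD40 (50.8 against 69.5 to 72.2) and HDAC9 (92.1 against 127.9 to 135). Control replicate 3 stood apart for ICOSLG (22.02 against 11.1 to 12.5) and MAPK13 (2.45 against 8.96 to 9.52).

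Other splits of the samples bear on the counts of changed genes. Of the 35 splits of the 7 samples into 4 and 3, only 1, the real split, reached its own counts. These were 298 changed genes, 138 higher, 160 lower and 143 changed at least 2-fold. The highest count of any other split was 0 for each. Every other split mixes control and knockout samples in a group, which by itself lowers its counts. A chance labelling of these 7 samples is argued against at 1 of 35, the smallest share possible. A chance difference between cultures or clones is not excluded. For gene lists the real split gave 1, and 17 of the 35 splits gave as many, with up to 3 in another split, so chance is not excluded for the number of lists past camera's threshold.

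Most of the tested genes, 68.19%, differed between the groups. Unequal counting noise from depth is argued against: 94.3% of the called genes were still called in the same direction after thinning to the shallowest library. The thinning was mild, with scaling factors of 0.63 to 1.29, and cannot test the amount or quality of RNA before counting. A different overall scaling is also argued against. Of the 204 genes called at 1.5-fold or more, 96.6% stayed so far apart under the single shift that leaves the fewest. Gain or loss of chromosome segments in the edited cells stays open: log2 fold changes of neighbouring panel genes correlated at a Spearman rho of 0.085 across 413 pairs (one-sided permutation p = 0.038), where under 0.1 with a p of at least 0.05 had been set to exclude it and 0.2 to favour it. Without pairs that share the first 3 letters of their symbol, rho was 0.048 (p = 0.156). An effect of the knockout and a difference between cell clones also stay open, since the labels do not give the number of clones.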

How the results depend on the processing

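Counts of changed genes stayed within 1.5 times of 298 in the alternatives run (249 at an adjusted p of 0.01 to 319 with no filter). At the threshold of 0.05, 258 to 298 of the same genes were shared, in the same direction. At that threshold the share of higher genes was 44.2% to 54.0%. Total counts moved the median log2 fold change by 0.102 and the other scalings by less. Scaling with positive controls and reference genes is the main scaling by construction and tests nothing. With 1 sample left out, changed genes numbered 276 to 294, higher genes 129 to 138, lower genes 142 to 158, genes changed at least 2-fold 140 to 145, and lists 1 to 1. Lists past the threshold numbered 0 with camera's estimated correlation and 16 with fry, which asks another question. For MHC class II the estimated correlation was -0.018, below the preset 0.01, so a larger correlation did not lose that call. The cause was not otherwise tested. Agreement with the authors' values was r = 0.9597 with a pseudocount of 20, which shrinks the changes of low genes by construction. Of 134 named genes, 124 kept direction and the call at 0.05 in each alternative that tested them, 114 of these in all 23, since 14 named genes were under the filter of 50 counts. The threshold of 0.01 is not among these 23. It removes the call of 9 named genes, 2 of them (BST2 and HRAS) otherwise kept. Of 3068 gene and alternative pairs 49 lost the call. VSIR reversed to a log2 fold change of -0.006594 with counts below 20 set to 20, which lifts its low control counts by construction. Whether replicate numbers pair the samples stays undecided. Deviations of samples of the same number correlated at 0.148, 0.034 and 0.222, all above 0, but not every sample correlated best with its own number. A replicate block gave 286 changed genes. Genes under the filter were not tested.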

Other observations

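The tests of the control samples and of the interferon genes were chosen after those patterns were seen. Some genes of retinoid metabolism outside the fixed lists were chosen after their values were seen. ALDH1A3, a retinaldehyde dehydrogenase, rose from 6025 ± 320 to 8915 ± 511 and DHRS3, a retinaldehyde reductase, from 1380 ± 126 to 2401 ± 149. The receptors RARA and RARB did not pass the test, at 129 ± 30.9 and 117 ± 13.8, and at 149 ± 42.7 and 138 ± 4.17.

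Notch genes held rises and a fall. HEY1, a Notch target, rose from 219 ± 25.3 to 927 ± 108 and JAG1, a Notch ligand, from 60.1 ± 18.2 to 256 ± 20.9, while HEY2 fell from 34.0 ± 3.89 to 9.30 ± 1.52. The 3 tested genes of hypoxia and angiogenesis rose, among them VEGFA from 307 ± 24.7 to 487 ± 32.9. PPARGC1A, a regulator of mitochondrial genes, fell from 182 ± 21.5 to 68.5 ± 11.9, and LDHA, a lactate dehydrogenase, from 7067 ± 1097 to 4076 ± 383. The immediate-early gene FOS was 17.9, 38.1, 1.22 and 10.2 in control replicates 1 to 4 and 61.6, 3.69 and 3.10 in the knockout replicates.

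The control samples differed among themselves along the axis that parts the groups, with first component scores of -13.0, -11.5, -15.6 and -16.2 for replicates 1 to 4 against 18.3, 19.4 and 18.6 in the knockout. IDO1 was 81.5, 111, 47.7 and 13.9 in these controls. Depth of the libraries stays open. After thinning, 101% of the control spread was kept, so unequal counting noise is argued against. Thinning keeps the expected normalized count of each gene, so it cannot test a difference that came with depth. The deepest and shallowest control lay 1 position apart on the axis, which on its own says little. Carried-over knockout RNA, which could raise such genes, should give equal shares from genes higher and lower in the knockout. In 5 of 6 pairs of controls the share from the lower genes was under 0.25 of that from the higher genes. The 95% intervals of the 2 shares, from resampling genes, also lay apart in these pairs. For replicate 1 against 4 they were -11.27% to -1.43% (lower genes) and 9.02% to 13.96% (higher genes). A small error in the scaling of a control can part the 2 shares in the same way. The intervals leave such an error out and treat genes as independent. Carry-over therefore stays open for those 5 pairs. Between replicates 2 and 1 (1.77% and 4.44%) it also stays open. No biological explanation was tested.

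Interferon-stimulated genes of the type I list moved in opposite directions. A single shift of all genes between the groups is argued against, since a log2 shift of at least 2.50 would be needed to give the 7 called genes 1 direction, against at most 0.71 in any reference gene. Rerunning with other library size scaling decided nothing: 0 of the 7 changed direction, but the 5 scalings moved the median by at most 0.102 where the smallest called change was 0.35. For values near the background of the assay, 7 of the 7 lay above the negative control threshold in every sample of their higher group. The filter on counts largely fixes that. But 6 also had both group means above it, among them MX1 and MX2, which fell, and BST2, which rose (277 to 954). This argues against background as the source of the opposite directions of these 6 genes. For RSAD2, at background in the controls, it stays open. An effect of the knockout stays open too, as an untested hypothesis.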
